A study of Arabidopsis thaliana with 10 samples.

How the data were processed

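Messenger RNA was sequenced from Arabidopsis thaliana of the Col-0 accession (wild type, WT) and from a mutant line of AHL13, a gene of the AT-hook motif nuclear-localised (AHL) family of DNA-binding proteins. Per the labels' protocols, plants grew in short days of 8 h light and 16 h dark at 75 uE. Seedlings 10 days old, on MS plates, were harvested untreated or 1 h after 100 nM flg22, a peptide of bacterial flagellin that is recognised as a pathogen-associated molecular pattern (PAMP) by the receptor kinase FLS2 (the labels write this concentration as nm). Leaves of plants 4 weeks old were inoculated with Pseudomonas syringae pv. tomato DC3000 at an OD600 of 0.0005 and collected 3 days later. Libraries were made from 1 ug of total RNA with an mRNA kit, per the labels.

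The seedling table holds 6 libraries: 2 of untreated WT, 2 of WT with flg22, and 1 each of untreated and flg22-treated ahl13. The leaf table holds 2 libraries of infected WT and 2 of infected ahl13. An uninfected leaf group is not analysed here, so the leaf comparison is between genotypes under infection and not a response to infection. Columns were matched to samples by the sample titles. The flg22-treated ahl13 seedling column carries another replicate number in its header than in the title of its sample, and the leaf columns do not name the bacterium; both were matched by genotype and treatment, which left no other choice. Nothing in the labels says that replicates came from separate cultures or plants, so p-values measure the spread between these samples, which may be technical.

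The authors deposited a count of reads per gene, not normalised, for each library, per the file headers and the values, which are whole numbers. Beside it the authors deposited FPKM, per the file headers. For leaves the authors also deposited a p-value and a log2 fold change per gene from edgeR, per the file headers; their version and settings are not given in the sources used here. Their sign was read from the counts as ahl13 relative to WT. Per the submitters' processing notes, the tools were fastp, Bowtie 0.12.2, TopHat2, Cufflinks and DESeq, without roles. The same notes name the build mm8, which is a mouse build and cannot be that of a table of Arabidopsis loci. The Arabidopsis build, annotation and counting rules used are not given in the sources used here, so no coordinates are printed. The TAIR10.1 reference served only for gene symbols, the order of loci and a search for loci that share sequence. The tables list 27821 genes for seedlings and 28000 for leaves, of which 405 and 372 are new loci that the authors numbered and that carry no annotation; these hold 0.856% to 2.03% of the counts in seedlings and 0.416% to 0.474% in leaves. No strand rule of the counting is known, so genes that overlap cannot be told apart.

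Exons of all 38074 loci with exons were aligned to each other with BLAST+ 2.17.0. A locus with another at 97% identity or more over 80% or more of its exons was taken as having a near-identical copy (1890 loci). Where 50% or more of the exons of a locus lay under another, both loci were taken as overlapping (4226 loci). Genes of either kind are named as such, since the counting could assign their reads to the partner.

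Total counts were 34334251 to 48264261 per seedling library and 40071051 to 44406348 per leaf library. Levels are printed as CPM, that is counts scaled to a common library total, after TMM scaling. A count of 3 in a library, the floor used here for an upper limit where the count is 0, is 0.0622 to 0.0874 CPM before TMM scaling; folds given as at least a value use 0.0763 CPM, the higher of the floors of the untreated WT libraries after TMM scaling. Such limits and all counting intervals cover counting error only. Replicates were compared before averaging: counts of replicates differed by a chi-square of 25.4 to 311 per gene, more than sampling noise, so no library was taken to be a repeat deposit of another; this does not show that replicates came from separate plants.

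Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default filter on low counts by group, robust dispersions, robust quasi-likelihood fits and F-tests, with Benjamini-Hochberg adjusted p under 0.05. This left 21707 genes in seedlings and 19250 in leaves. The 6 seedling libraries were fitted together with 4 group means, from which the flg22 response of WT, the genotype difference in untreated and in flg22-treated seedlings and the difference between the responses were taken. These fits have 2 residual degrees of freedom, all from WT, and each single ahl13 library is assumed to vary like WT. A further fit with genotype and treatment as terms gave the ahl13 effect over both treatments. The 4 leaf libraries were fitted separately. The flg22 response of ahl13 is a fold between 2 libraries with no test. Its size was compared with that of a WT pair over genes chosen by the other WT pair. Choosing and comparing on the same libraries would make ahl13 look weaker. Slopes were taken through the origin against the change in the choosing pair.

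There were 19 gene lists with 424 entries, of which 423 matched the reference and 1 was dropped. They cover early PAMP-induced genes, PAMP receptors and early signalling, salicylic acid and systemic resistance, jasmonate biosynthesis, jasmonate signalling and response, ethylene and jasmonate-ethylene defence, camalexin and tryptophan pathway, indole glucosinolates, aliphatic glucosinolates, phenylpropanoid and lignin, flavonoid and anthocyanin, abscisic acid and cold or drought response, auxin response, nuclear-encoded photosynthesis, senescence, the AHL family and 3 checks: heat shock for handling, the circadian clock for harvest time and root markers for the mix of organs. Each list was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation and with fry. Fry tests whether the genes of a list move, on balance, in a single direction and does not compare them with other genes. Camera with an estimated correlation and fry passed no list in any comparison fixed before, the flg22 response of WT included. Failing them therefore does not show that a list is unchanged. Members past adjusted p 0.05 were counted over all genes tested and adjusted over the list alone.

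The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. By that rule the text names AHL13 and the loci on each side of it, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between groups (5 and 5 for the difference between responses), or the 5 lowest p if fewer than 5 passed, and up to 4 members of each list with the lowest p. From these the text takes the examples that describe each group; one result for a gene withheld for evaluation is not reported here. Genes outside the rule are said to have been chosen after their values were seen.

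The tests were run on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. In leaves, 82 of the 100 genes changed 2-fold and 99 of the 100 changed 4-fold were called, with 22 false calls among 203. For the flg22 response of WT, 0 of 100 were called at either fold, and 3 calls were false. For the ahl13 effect over both seedling treatments, 0 of 100 were called at 2-fold and 22 of 100 at 4-fold, with 2 false calls among 24. For the difference in untreated seedlings, the difference in flg22-treated seedlings and the difference between responses, 0 of 100 were called at either fold. The seedling fits can thus call only changes well above 4-fold or of low spread, and a gene not called there is not shown to be unchanged. Simulated counts follow the fitted dispersions, which may make them easier than the real data. In the real leaf fit 8 genes passed and CHS, at log2 -1.12, did not. A leaf gene not called is therefore not shown to be unchanged either.

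Alternatives were RLE and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in 2 libraries, organelle and ribosomal RNA genes left out, a fit of the 4 WT libraries alone, the replicate number as a block, each library left out in turn, limma-voom, DESeq2 1.42.0 and limma-trend on log2(FPKM + 1). After the data were seen, fits without either WT seedling pair and a fit of the flg22 response over 3 pairs (2 WT and 1 ahl13) were added. Tests of the biological process terms that the leaf table gives for its genes were also added, used for both settings, for terms of 15 to 300 genes. Each fit without a WT pair holds 4 libraries, a single library per genotype and treatment, with 1 residual degree of freedom. Its p-values and calls therefore rest on how the genotype difference varies between treatments and not on replicates.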

Results

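RNA-seq counts were compared between WT and ahl13 in 2 settings that bear on how the AHL13 protein acts in immunity: seedlings 10 days old, untreated or 1 h after flg22, and leaves of plants 4 weeks old, 3 days after inoculation with the virulent bacterium Pseudomonas syringae pv. tomato DC3000. WT seedlings were sampled as 2 libraries per treatment with 37478264 and 48264261 total counts untreated and 34334251 and 36469579 after flg22. Each ahl13 seedling group was a single library, with 37423350 total counts untreated and 45237861 after flg22, and so has no replicate check. Leaves were sampled as 2 libraries per genotype, with 40071051 and 44406348 total counts in WT and 42292978 and 40302635 in ahl13.

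AHL13 (AT4G17950) transcript was lower in every ahl13 library than in every WT library of the same condition (untreated seedlings, flg22-treated seedlings or infected leaves), and it was not lost in any. In untreated seedlings it was at 29.7 CPM ± 1.78 (SD, n = 2) in WT and 8.39 CPM in ahl13, or 28.3% of WT. After flg22 it was at 34.5 and 54.9 CPM in WT and 11.1 CPM in ahl13, or 24.7%. In infected leaves it was at 18.9 CPM ± 3.19 (SD, n = 2) in WT and 8.60 CPM ± 1.03 (SD, n = 2) in ahl13, or 45.6%. Counts per gene do not show whether the reads left in ahl13 come from whole or partial AHL13 transcripts. The leaf log2 fold change of AHL13 was -1.13 with SE 0.17 and an edgeR adjusted p of 0.176, so it did not pass over all genes tested; adjusted over the list alone, AHL13 was the 1 member of the AHL family that was lower. The seedling log2 fold change over both treatments was -1.92 with SE 0.27, also short of the threshold (edgeR adjusted p = 0.98). In fits added after the data were seen it was -2.04 without the WT replicate 1 pair and -1.82 without the replicate 2 pair. Those fits hold a single library per genotype and treatment, so they have no replicate check. The gene next to it on one side, AT4G17940, was at 80.6%, 62.0% and 71.9% of WT in untreated seedlings, flg22-treated seedlings and leaves (leaf log2 -0.48, SE 0.12, edgeR adjusted p = 0.372). AT4G17960 on the other side was at 99.9%, 73.3% and 101%.

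**Figure D1:**
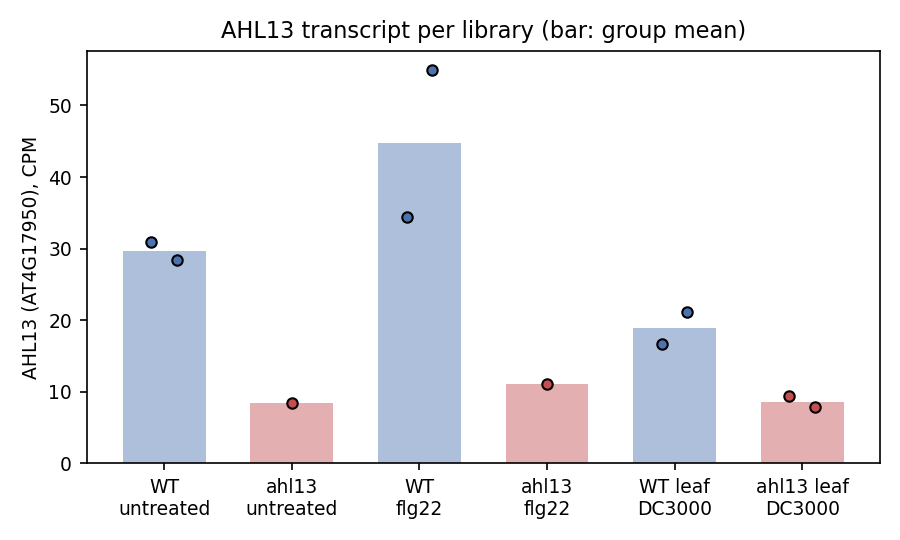
AHL13 transcript in CPM in each library (points) with the group mean (bar) for WT (blue) and ahl13 (red) in the 3 conditions. Every ahl13 point, from 7.88 to 11.1 CPM, lies below every WT point, from 16.6 to 54.9 CPM.

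The flg22 comparison in WT asks which transcripts respond to a bacterial pattern within 1 h. In WT seedlings 126 genes passed as higher, each by at least 2-fold, and 0 as lower, out of 21707 tested with edgeR at an adjusted p under 0.05 (n = 2 per group). Other fits of these libraries also called genes lower. The largest rises included defence regulators and enzymes that were near the detection limit before treatment. WRKY30 (AT5G24110), a pattern-induced transcription factor, went from 0 in both untreated libraries to 139 and 60.5 CPM, at least 792-fold higher against a floor of 3 counts per library. CYP82C3 (AT4G31950), a cytochrome P450, rose at least 222-fold by the same floor, from 0 in both to 26.3 and 16.9 CPM. PP2-B14 (AT1G56250), which encodes an F-box protein with a phloem protein domain, rose from 0.10 and 0.15 to 113 and 109 CPM (log2 9.75, SE 0.46, edgeR adjusted p = 0.032). The phosphatase gene AT1G07160 went from 0.05 and 0.13 to 64.1 and 104 CPM, and AT1G56060 from 0 and 0.06 to 53.2 and 38.0 CPM. Of the 126 genes, 16 have a near-identical copy or overlap another gene and are uncertain for that reason.

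Early PAMP-induced genes lay higher as a group. All 39 had a positive sign, with a median log2 change of 3.72, also with WRKY30 at its bound. Of these 8 rose over all genes tested and 26 when adjusted over the list alone. FOX1, a berberine bridge enzyme-like oxidase, rose from 0.25 in both to 196 and 59.1 CPM (log2 8.96, SE 0.86, edgeR adjusted p = 0.044), PUB22, a U-box ubiquitin ligase that damps immune signalling, by log2 5.64 (SE 0.60, edgeR adjusted p = 0.044), and WRKY22, a transcription factor downstream of MAP kinases, by log2 4.72 (SE 0.47, edgeR adjusted p = 0.044). Of the PAMP receptors and early signalling genes all 28 had a positive sign, with a median of 2.23. Of these 3 rose over all genes tested and 22 adjusted over the list alone. EFR, the receptor of bacterial elongation factor Tu, rose by log2 4.07 (SE 0.41), XLG2, an extra-large G protein, by 3.08 (SE 0.34), and BIK1, the kinase that acts with FLS2, by 3.12 (SE 0.35), at edgeR adjusted p of 0.044, 0.046 and 0.047. Against all other genes both lists passed camera at the preset correlation (adjusted p = 3.9e-40 and 5.2e-27), but not with the correlation estimated (adjusted p = 0.269 with an estimated correlation for both).

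Of the hormone and secondary metabolite lists, 5 also lay higher after flg22. In jasmonate biosynthesis 2 of 14 genes rose over all genes tested and 5 adjusted over the list alone: the allene oxide cyclases AOC1 (log2 3.47, SE 0.36, edgeR adjusted p = 0.044) and AOC3 (5.53, SE 0.44, edgeR adjusted p = 0.038) were the 2; the list median was 0.91. Of 29 jasmonate signalling genes 0 passed edgeR over all genes and 7 adjusted over the list alone (median 1.16). JAZ6, a repressor of jasmonate responses, was at log2 3.03 with an edgeR adjusted p of 0.053. Of 31 salicylic acid genes 0 passed edgeR over all genes and 5 adjusted over the list alone, among them EDS5 (log2 3.31), the exporter of the salicylic acid precursor from the plastid, and EDS1 (log2 2.06), an immune lipase-like protein; the median was 1.59. In the camalexin and tryptophan list 1 of 17 rose, GSTF6, a glutathione transferase of camalexin synthesis (log2 6.78, SE 0.63, edgeR adjusted p = 0.044), and 11 adjusted over the list alone; the median was 2.18 and the exporter PEN3 was at 3.495 (edgeR adjusted p = 0.067). Of 14 indole glucosinolate genes 0 passed edgeR over all genes and 7 adjusted over the list alone, with a median of 1.79. CYP81F2, which hydroxylates indole glucosinolates, was at log2 5.93 (edgeR adjusted p = 0.095) and the myrosinase PEN2 at 3.26 (edgeR adjusted p = 0.078). All 5 lists passed camera at the preset correlation (adjusted p from 3.6e-11 to 1.4e-05) and none with it estimated (adjusted p = 0.436 with an estimated correlation, 0.527 for jasmonate biosynthesis). In the ethylene list 1 of 20 genes rose, ACS7, an enzyme of ethylene synthesis (log2 6.54, SE 0.73, edgeR adjusted p = 0.047), and the list did not pass camera (adjusted p = 0.0703).

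Other lists lay lower after flg22 by camera at the preset correlation only. Aliphatic glucosinolate genes had a median of -1.80, with 13 of 15 negative (camera adjusted p = 1.4e-05, adjusted p = 0.527 with an estimated correlation), and 0 passed edgeR, either over all genes or adjusted over the list alone. FMOGSOX3, a flavin monooxygenase of side chain oxidation, was at log2 -3.16 (edgeR adjusted p = 0.32) and the sulfotransferase SOT18 at -1.80 (edgeR adjusted p = 0.27). Auxin response genes had a median of -1.50, with 16 of 20 negative (camera adjusted p = 0.00012, adjusted p = 0.305 with an estimated correlation). Of these 0 passed edgeR over all genes, and adjusted over the list alone 8 were lower and 1 higher. Among them the growth-related SAUR21 was at log2 -2.86 (edgeR adjusted p = 0.17), the auxin conjugating enzyme GH3.6 at -2.11 and the repressor IAA3 at -1.28 (edgeR adjusted p = 0.21 for both). All 37 nuclear-encoded photosynthesis genes were negative, with a median of -0.51 (camera adjusted p = 0.0019, adjusted p = 0.701 with an estimated correlation) and 0 past edgeR by either adjustment. The antenna protein gene LHCB4.2 was at -1.36 (edgeR adjusted p = 0.47). Without the untreated WT replicate 2 library that median was 0.023, and without the flg22-treated WT replicate 1 library it was -0.24 and did not pass. The phenylpropanoid and lignin list (median 0.10, camera adjusted p = 0.0809; C4H, log2 1.31, edgeR adjusted p = 0.26), the flavonoid and anthocyanin list (-0.63, 0.161), the abscisic acid list (-0.32, 0.525; NCED3, log2 -2.53, edgeR adjusted p = 0.44), senescence (0.21, 0.683), root markers (-0.11, 0.419) and the AHL family (0.18, 0.787) did not pass.

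Heat shock genes, listed as a check of handling, differed between the WT pairs. Their median was 2.97 (10 of 11 positive, camera adjusted p = 0.00027, adjusted p = 0.486 with an estimated correlation), but 4.21 in the replicate 1 pair and 0.27 in the replicate 2 pair; without the flg22-treated replicate 1 library it was 0.69 and did not pass. The chaperone gene HSP90.1 went from 8.02 and 11.2 to 243 and 16.7 CPM. Circadian clock genes had a median of -0.57 (15 of 18 negative, camera adjusted p = 0.0314, adjusted p = 0.436 with an estimated correlation), and this call was lost without the untreated replicate 2 library (-0.15) or the flg22-treated replicate 1 library (-0.72). FRK1, a receptor kinase gene often used to follow flg22 responses and chosen here after its values were seen, went from 0.10 to 30.2 CPM in replicate 1 and from 0.69 to 0.82 CPM in replicate 2.

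The count of 126 rests on all 4 WT libraries, since 0 genes passed without any one of them, whether untreated replicate 1 or 2 or flg22-treated replicate 1 or 2. At an unadjusted p under 0.05 there were 2503 genes, against 1085 by chance. DESeq2 called 1361 higher and 159 lower, and a fit over 3 pairs with the ahl13 pair included, added after the data were seen, 1982 higher and 1438 lower. The fit with the replicate number as a block called 1055 higher and 120 lower.

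**Figure D2:**
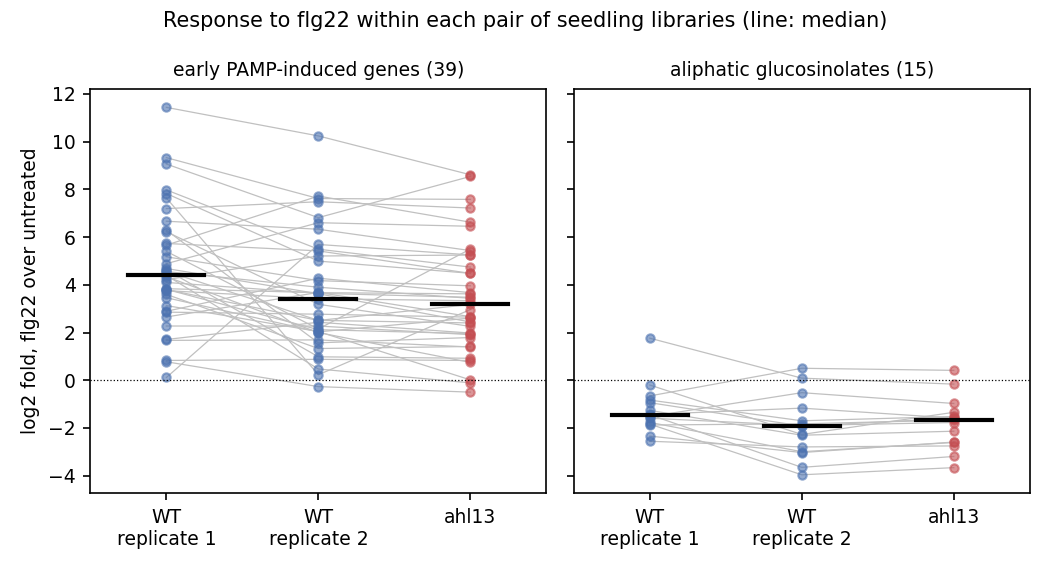
Response to flg22 (log2 fold over untreated) of each gene of 2 lists within the 2 WT pairs (blue) and the ahl13 pair (red), with lines joining a gene and a black bar at the median. Medians of the 39 early PAMP-induced genes are 4.40, 3.42 and 3.17, and most of the 15 aliphatic glucosinolate genes lie below 0 in all 3 pairs.

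Whether ahl13 seedlings respond to flg22 as WT does was examined next. In the single ahl13 pair the medians of 5 lists had the sign they had in both WT pairs, though not every member followed. Early PAMP-induced genes had a median log2 change of 3.17 in the ahl13 pair, against 4.40 and 3.42 in the WT pairs, and 33 of 39 were at least 2-fold higher, against 36 and 34. PAMP receptors and early signalling genes had a median of 1.70, aliphatic glucosinolate genes -1.67, auxin response genes -1.35 and photosynthesis genes -0.55. WRKY30 went from 0.10 to 59.0 CPM, PP2-B14 from 1.14 to 109 CPM, FOX1 from 0.23 to 52.9 CPM, and AT1G07160 from 0.15 to 112 CPM. FRK1 went from 0.38 to 3.29 CPM. Changes of at least 4-fold were seen for 1218 genes upward and 516 downward, against 1632 and 381 in the WT replicate 1 pair and 1382 and 579 in the replicate 2 pair. With 1 library per group these folds have no replicate check.

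The size of the response was compared with that of a WT pair that took no part in choosing the genes. Each slope was taken through the origin against the change in the choosing pair. Over 3179 genes chosen by the replicate 1 pair, the slope of the ahl13 response was 0.926 times that of the replicate 2 pair. Over 3154 genes chosen by the replicate 2 pair it was 1.04 times that of the replicate 1 pair. These slopes pool rises and falls. Among rises the ahl13 median was 1.37 against 1.42 in the other WT pair for the first set, and 1.78 against 1.91 for the second. Among falls it was -0.66 against -0.61 and -1.25 against -0.63. A ratio near 1 therefore does not show an equal response. The ratio also depends on how closely each response follows that of the choosing pair. The sign of the change was that of the choosing pair for 88.5% and 98.2% of genes in ahl13, and for 86.5% and 86.7% in the other WT pair. Across genes, which are not independent replicates, responses correlated at 0.800 between ahl13 and WT replicate 2, 0.579 between ahl13 and WT replicate 1 and 0.586 between the WT pairs.

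Tested directly, the difference between the responses passed for 0 genes with edgeR, with 50 genes at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 12. The lowest p belonged to PGLP1 (phosphoglycolate phosphatase, of photorespiration), which did not pass (edgeR adjusted p = 0.334) and has a near-identical copy. It was at 0 in flg22-treated ahl13 and between 106 and 149 CPM in the other 5 libraries. Early PAMP-induced genes responded less in ahl13 by a median log2 of -0.36 (32 of 39 negative, camera adjusted p = 1.3e-05), as did indole glucosinolate genes (-1.03, 7.3e-06), PAMP receptors and early signalling genes (-0.31, 0.0014), salicylic acid genes (-0.45, 0.0014), camalexin genes (-0.39, 0.0059), phenylpropanoid genes (-0.28, 0.0151) and heat shock genes (-1.45, 0.0014), while ethylene genes lay higher (0.28, 0.0469). None of these 8 lists passed with the correlation estimated (adjusted p = 0.884 with an estimated correlation) or with fry. Without the untreated WT replicate 2 library 14 lists passed. Directions turned for early PAMP-induced genes without the untreated WT replicate 1 library (0.052) or the flg22-treated WT replicate 2 library (0.27). Heat shock genes turned without the flg22-treated WT replicate 1 library (0.44). Phenylpropanoid (0.082) and ethylene genes (-0.0037) turned without the untreated WT replicate 1 library. Without that library the salicylic acid (-0.18), camalexin (-0.22) and indole glucosinolate lists (-0.52) also lost their calls. Each such fit leaves a WT pair in only 1 treatment, so the difference between the WT pairs enters the response. Against each whole WT pair the early PAMP median of the single ahl13 pair was lower, at 3.17 against 4.40 and 3.42.

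Genotypes were then compared within seedlings, where AHL13 itself and a few other transcripts were lower in ahl13, none past the threshold. Over both treatments 0 genes passed with edgeR at 180 genes with an unadjusted p under 0.05, where 1085 would arise by chance. Limma-voom called 0, DESeq2 15 and the fit with the replicate number as a block 1808 (1326 higher and 482 lower). That block sets ahl13, labelled replicate 1, against the WT replicate 1 pair. Fits added after the data were seen called genes with either WT pair left out, but they hold a single library per genotype and treatment. The lowest p values belonged to IAA16, a repressor of auxin responses (log2 -3.05, SE 0.28, edgeR adjusted p = 0.935), to BZIP53, a transcription factor gene of low energy responses, to AT5G24240, annotated as a phosphatidylinositol 4-kinase (log2 -6.54, SE 0.92, edgeR adjusted p = 0.98), and to AHL13. BZIP53 was at 64.8 CPM in flg22-treated ahl13 and at 0 to 0.03 CPM in the other 5 seedling libraries. In untreated seedlings 0 genes passed with edgeR (72 at an unadjusted p under 0.05, 0 with limma-voom, 13 with DESeq2). After flg22 the count was also 0 (72, 0 and 15). Among the lowest p were SAE1B, SPL13B and AT2G05250, whose reads can be shared with near-identical copies. SAE1B, a subunit of the SUMO activating enzyme, was at 0 in both untreated WT libraries and 21.2 CPM in untreated ahl13, SPL13B, a transcription factor of the vegetative phase, at 14.1 and 10.4 against 0 CPM, and AT2G05250 at 0.33 CPM in untreated ahl13 and 18.5 to 24.8 CPM in the other 5 libraries.

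List differences between genotypes in seedlings went with a difference of the WT replicate 1 pair from the other 4 libraries. Over both treatments abscisic acid genes (median log2 0.67, 23 of 26 positive, camera adjusted p = 2.7e-05), root markers (0.85, 17 of 20, 2.7e-05), flavonoid genes (0.80, 0.0014) and aliphatic glucosinolate genes (0.53, 15 of 15, 0.0014) lay higher in ahl13. None passed with the correlation estimated (adjusted p = 0.840 with an estimated correlation) or with fry. Within WT, replicate 2 exceeded replicate 1 in the same lists, untreated and after flg22, by medians of 2.25 and 2.54 for abscisic acid genes, 2.44 and 3.10 for root markers, 3.03 and 2.33 for flavonoid genes and 1.97 and 1.402 for aliphatic glucosinolate genes. Against WT replicate 2 alone, the ahl13 medians were -0.094 and 0.14, 0.082 and 0.25, -0.033 and 0.043, and -0.16 and 0.069. With the WT replicate 1 pair left out, the 4 lists did not pass and the aliphatic median turned to -0.067. The number of lists past camera was 8 without either WT replicate 2 library, 9 without the flg22-treated ahl13 library, 3 without the untreated WT replicate 1 library and 4 as fitted. In untreated seedlings alone 9 lists passed camera and 0 did without the untreated WT replicate 1 library (adjusted p = 0.708 with an estimated correlation for all 9). After flg22 6 lists passed, 1 without the WT replicate 1 library and 11 without the WT replicate 2 library (adjusted p = 0.980 with an estimated correlation).

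**Figure D3:**
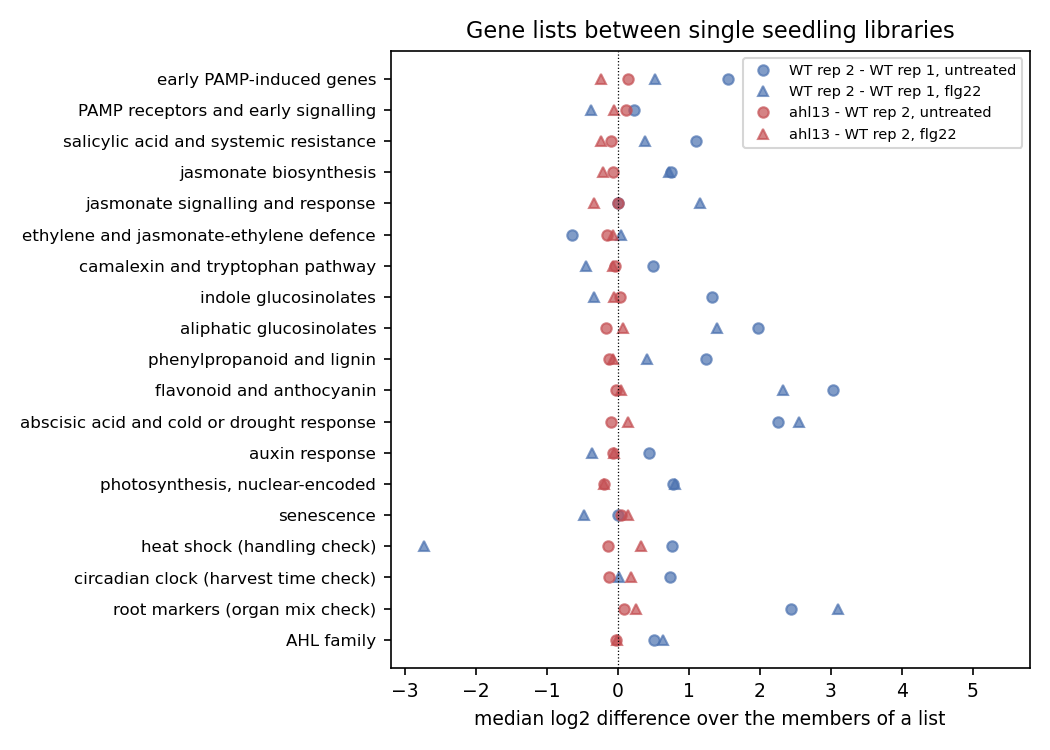
Median log2 difference over the members of each list between WT replicate 2 and WT replicate 1 (blue) and between ahl13 and WT replicate 2 (red), for untreated (circles) and flg22-treated (triangles) seedlings. Root markers differ by 2.44 and 3.10 between the WT replicates and by 0.082 and 0.25 between ahl13 and WT replicate 2.

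In leaves infected with DC3000, 3 genes were higher and 5 lower in ahl13 than in WT, out of 19250 tested with edgeR (n = 2 per group). IAA16 fell by 3.56 on the log2 scale (SE 0.11, edgeR adjusted p = 1.5e-05), from 96.0 and 92.3 CPM in WT to 8.21 and 7.75 in ahl13. AT3G05220, annotated as a heavy metal-associated protein, fell by 2.88 (SE 0.11, 2.1e-05), from 146 and 140 to 18.7 and 20.2 CPM. AT5G11330, a monooxygenase, fell by 1.71 (SE 0.10, 0.00058), from 102 and 104 to 32.6 and 30.2 CPM, and AT5G24240 by 5.42 (SE 0.31, 0.0158), from 128 and 151 to 2.22 and 4.29 CPM. AT14A (AT3G28290), an integrin-like protein, was higher, at 0 and 0.05 CPM in WT and 78.1 and 61.8 in ahl13, and has a near-identical copy. The unannotated new locus 301 of the authors' table was also higher, at 0.20 and 0.48 against 14.4 and 14.7 CPM (log2 5.38, SE 0.32, edgeR adjusted p = 0.00058). The other two calls, AT4G09435 (lower, edgeR adjusted p = 0.0033) and AT1G64795 (higher, edgeR adjusted p = 0.0032), overlap other genes, lie under the level set for named genes and were chosen after their values were seen.

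The leaf calls were few while 1953 genes had an unadjusted p under 0.05, against 962 by chance. DESeq2 called 59 higher and 133 lower, which include 6 of the 8, the other two having no adjusted p there. Leaving out WT replicate 2 gave 946 calls (456 higher and 490 lower), WT replicate 1 20, and ahl13 replicate 2 13. AT5G24240 did not pass without WT replicate 1 (log2 -5.54, edgeR adjusted p = 0.39), and AT1G64795 did not pass without either ahl13 library (edgeR adjusted p = 0.058 and 0.069). In the authors' deposited table for leaves, 166 genes were higher and 278 lower at a p under 0.01 and 1.5-fold, and Benjamini-Hochberg adjustment of those p-values left 81 and 149; all 8 genes called here pass there.

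Flavonoid and anthocyanin genes lay lower together in infected ahl13 leaves. Of 14 measured, 13 were negative with a median log2 change of -0.81. Of these 0 passed edgeR over all genes, and 10 were lower adjusted over the list alone. Chalcone synthase (CHS), the entry enzyme, was at -1.12 (SE 0.15, edgeR adjusted p = 0.13), the anthocyanin glycosyltransferases UF3GT and UGT75C1 at -0.95 (SE 0.11, edgeR adjusted p = 0.053) and -0.86 (SE 0.12, edgeR adjusted p = 0.15), and the anthocyanin malonyltransferase 5MAT at -1.27 (SE 0.16, edgeR adjusted p = 0.09). Of these, UGT75C1 overlaps another gene. The list passed camera at the preset correlation (adjusted p = 2.2e-26) but not with it estimated (adjusted p = 0.496 with an estimated correlation). Between libraries of the same number the median was -0.76 and -0.83, while the WT libraries differed from each other by -0.15.

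**Figure D4:**
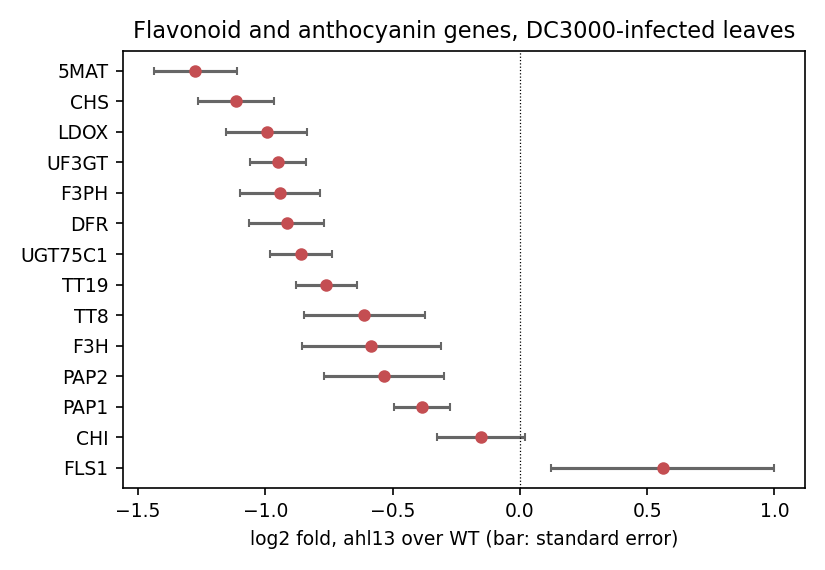
Log2 fold change between ahl13 and WT in infected leaves for the 14 measured flavonoid and anthocyanin genes, with bars at the standard error. Of the 14, 13 lie below 0, with UF3GT at -0.95 and 5MAT at -1.27.

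Photosynthesis genes lay lower and defence genes higher in infected ahl13 leaves, with list medians of less than 2-fold. All 37 photosynthesis genes were negative, with a median of -0.51 (camera adjusted p = 1.0e-21, adjusted p = 0.496 with an estimated correlation) and 0 past edgeR by either adjustment. The antenna gene LHCA2 was at -0.59 and the Rubisco small subunit RBCS3B at -0.74 (edgeR adjusted p = 0.42 for both). The WT libraries differed from each other by nearly as much, with a median of -0.47. All 33 salicylic acid genes were positive, with a median of 0.37 (camera adjusted p = 5.6e-13, adjusted p = 0.496 with an estimated correlation), and 0 passed edgeR by either adjustment. NIMIN1, an interactor of the salicylic acid receptor NPR1, was at 1.01 (edgeR adjusted p = 0.39) and WRKY62 at 0.67 (edgeR adjusted p = 0.40). Early PAMP-induced genes had a median of 0.39, with 34 of 36 positive (camera adjusted p = 6.5e-10, adjusted p = 0.496 with an estimated correlation). Of these 0 passed edgeR over all genes and 1 was higher adjusted over the list alone, the ubiquitin ligase PUB23 (0.67, SE 0.13, edgeR adjusted p = 0.31). FRK1 was at 0.92 (SE 0.22, edgeR adjusted p = 0.40), with 45.5 and 73.5 CPM in WT and 117 and 109 in ahl13. The WT libraries differed from each other by a median of 0.20 in the salicylic acid list and 0.36 in the early PAMP list. PAMP receptors and early signalling genes had a median of 0.20 (25 of 28 positive, camera adjusted p = 3.5e-06, adjusted p = 0.496 with an estimated correlation), with the MAP kinase kinase MKK4 at 0.39 (edgeR adjusted p = 0.40). None of these lists passed with fry.

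Of the other lists in leaves, aliphatic glucosinolate genes lay lower (median -0.25, 15 of 15 negative, camera adjusted p = 1.3e-06, adjusted p = 0.496 with an estimated correlation), with the regulator MYB29 the 1 that was lower adjusted over the list alone (-0.70, SE 0.12, edgeR adjusted p = 0.25). Senescence genes lay higher (0.30, 13 of 14 positive, camera adjusted p = 6.3e-05, adjusted p = 0.496 with an estimated correlation), with the transcription factor NAP the 1 that was higher adjusted over the list alone (0.56, edgeR adjusted p = 0.36). Phenylpropanoid genes (0.22, 0.0053; C4H, 0.54, edgeR adjusted p = 0.40) and ethylene genes (0.22, 0.0238) passed camera too, but not with the correlation estimated (adjusted p = 0.620 and 0.496 with an estimated correlation). The phenylpropanoid call was lost without WT replicate 1 (0.15) or ahl13 replicate 1 (0.090), and the ethylene call without WT replicate 1 (0.14), ahl13 replicate 1 (0.19) or ahl13 replicate 2 (0.17). Jasmonate biosynthesis (-0.12), jasmonate signalling (-0.11; the chlorophyllase CLH1, -0.61, edgeR adjusted p = 0.36) and auxin response (-0.21) did not pass camera (adjusted p = 0.170 for each). Nor did camalexin genes (0.085, 0.159), indole glucosinolate genes (0.044, 0.740), abscisic acid genes (0.052, 0.872), heat shock (0.19, 0.446), the circadian clock (0.012, 0.575), the 5 measured root markers (-0.19, 0.631) and the AHL family (0.071, 0.740). For indole glucosinolate genes, abscisic acid genes and the AHL family the test pointed down though the median was above 0. In the indole list CYP81F4 was the 1 member lower adjusted over the list alone (-1.09, SE 0.22, edgeR adjusted p = 0.33); it overlaps another gene.

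The genotype differences in seedlings and leaves share no library, and were compared over 18598 genes tested in both. With edgeR 0 genes passed in both, since 0 passed in seedlings. At an unadjusted p under 0.05, 10 genes were lower in both, AHL13 itself among them, against 3.81 by chance (one-sided Fisher exact p = 0.0044). Higher in both were 6, against 2.28 (one-sided Fisher exact p = 0.0255). The Fisher tests of this comparison treat genes as independent, which they are not. Fold changes over all genes did not correlate (Pearson r 0.029, Spearman rho -0.0226, across genes, which are not independent replicates). With the WT replicate 1 seedling pair left out, IAA16 and AT5G24240 passed in both (one-sided Fisher exact p = 1.5e-05), and at an unadjusted p 136 genes were lower in both against 60.6 by chance (one-sided Fisher exact p = 1.5e-19) and 45 higher against 39.4 (one-sided Fisher exact p = 0.195). With the WT replicate 2 seedling pair left out instead, 0 genes passed in both, and at an unadjusted p 84 genes were lower in both against 108 by chance (one-sided Fisher exact p = 0.996) and 118 higher against 76.5 (one-sided Fisher exact p = 1.0e-06), so the direction of the excess depends on the WT pair.

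Of 13564 genes compared in every library, 4 were at least 2-fold lower in every ahl13 library than in every WT library of the same condition, with untreated and flg22-treated seedlings compared separately, and 0 were higher. They were IAA16, AT3G05220, AT5G11330 and AT5G24240, with smallest folds of 6.50, 6.33, 2.02 and 29.8. In seedlings IAA16 was at 156 to 201 CPM in WT and at 17.7 and 24.0 CPM in ahl13, and AT3G05220 at 228 to 353 CPM in WT and 36.0 and 12.7 CPM in ahl13. AT5G11330 was at 29.3 to 58.9 CPM in WT seedlings and 22.4 and 6.96 CPM in ahl13, and AT5G24240 at 27.9 to 326 CPM in WT and 0.66 and 1.07 CPM in ahl13. At a limit of 1.5-fold 6 genes were lower in every library and 0 higher.

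**Figure D5:**
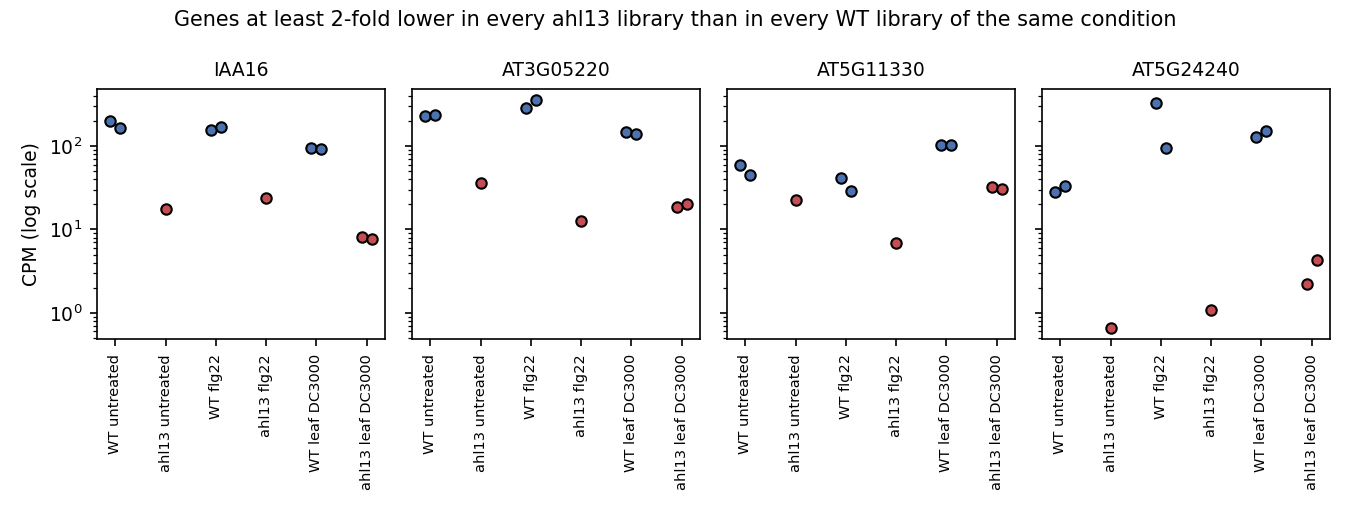
CPM on a log axis of the 4 genes that were at least 2-fold lower in every ahl13 library (red) than in every WT library (blue) of the same condition, with untreated and flg22-treated seedlings compared separately, a point per library. The smallest gap of a gene over the conditions is narrowest for AT5G11330, at 2.02-fold, and widest for AT5G24240, at 29.8-fold.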

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

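The differences between seedlings and leaves in this part were not tested, and no test here was chosen after the result was seen. For 4 named genes and 1 list, every ahl13 library of infected leaves lay on one side of its WT libraries and every ahl13 library of seedlings on the other side of the WT libraries of the same treatment, in some cases narrowly. CHS was lower in ahl13 leaves (log2 -1.12) and higher in ahl13 seedlings (1.05 over both treatments). The mean of the flavonoid and anthocyanin list, which contains CHS, was -0.69 in leaves and above 0 in seedlings. CYP81F4, which overlaps another gene, was at -1.09 in leaves and 0.93 in seedlings. PEN2 was at -0.070 in leaves and 0.28 in seedlings, and AT2G05250, which has a near-identical copy, at 0.12 in leaves and -1.98 in seedlings. The seedling values rest on the 4 WT libraries together. Those of CHS and CYP81F4 come from the WT replicate 1 pair, which also stood apart in the flavonoid list: CHS after flg22 was at 1.68 CPM in replicate 1, 31.0 in WT replicate 2 and 31.0 in ahl13, and CYP81F4 at 47.4 and 37.8, 264 and 227, and 283 and 263 CPM. PEN2 in untreated seedlings was at 170 CPM in ahl13 and 168 in WT replicate 2. The value of AT2G05250 comes from untreated ahl13 at 0.33 CPM, while after flg22 ahl13 was at 18.5 CPM against 24.8 and 18.6 in WT.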

How the results depend on the processing

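Fits without a WT seedling pair and the fit over 3 pairs were the only alternatives chosen after the result was seen. Counts of calls in the order flg22 response of WT, ahl13 effect over both seedling treatments, untreated, flg22-treated, difference between responses and leaves were 126, 0, 0, 0, 0 and 8 as reported, and 1520, 15, 13, 15, 12 and 192 with DESeq2. With the replicate number as a block they were 1175, 1808, 58, 81, 2 and 274; of the 1175, 1055 were higher and 120 lower, and of the 1808, 1326 and 482. Deviations of samples of the same number correlated at 0.493 in seedlings and 0.105 in leaves, so those seedling samples deviate together. The seedling column headers also carry codes with consecutive numbers within each WT pair and within the ahl13 pair. These could mark pairs, but the sources used here do not say what they mark. No sample label pairs samples by number and 2 pairs each are too few to decide it, so the block stays an alternative. Without a filter on low counts the flg22 response had 375 calls, and over 3 pairs, with ahl13 included, 3420. With the WT replicate 1 pair left out the ahl13 effect over both treatments had 73 calls (37 higher, 36 lower), and with the replicate 2 pair left out 59 (55 higher, 4 lower). Leaving out each library in turn gave 0 to 183 calls for the flg22 response and 11 to 946 for leaves. RLE and upper-quartile scaling, the CPM filter, removal of organelle genes, limma-voom and limma-trend moved no count of calls by more than 1.5 times. The genes called could still differ: of the 126 calls of the flg22 response, limma-voom kept 91 and limma-trend 106. Upper-quartile scaling shifted the median of all genes in the flg22 response from -0.07 to -0.18.

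Lists past the threshold, in the same order, were 12, 4, 9, 6, 8 and 9, and 0 in all 6 comparisons both with an estimated correlation and with fry. That includes the flg22 response of WT, where early PAMP-induced genes had a median log2 change of 3.72. Those alternatives thus missed even that response, so failing them does not tell an absent list effect from a present one. The ahl13 effect over both treatments had 9 with the block, 9 with the WT replicate 2 pair left out, and 3 to 9 as each library was left out; untreated seedlings had 0 to 11, flg22-treated seedlings 2 without the filter and 1 to 11, and the difference between responses 8 to 14. Genes at an unadjusted p in both seedlings and leaves were 16, and genes past the adjusted p in both 2 with the WT replicate 1 pair left out, against 0.

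List medians turned sign for aliphatic glucosinolates over both treatments (-0.067 with the WT replicate 1 pair left out) and as single libraries were left out. These ranges were -0.82 to 0.023 for photosynthesis in the flg22 response of WT; -0.10 to 1.00 for salicylic acid, -0.16 to 1.92 for aliphatic glucosinolates, -0.12 to 1.04 for phenylpropanoids, -0.036 to 3.81 for flavonoids and -0.094 to 2.37 for abscisic acid in untreated seedlings; -2.39 to 0.34 for heat shock in flg22-treated seedlings. For the difference between responses they were -1.55 to 0.27 for early PAMP-induced genes, -0.0037 to 0.76 for ethylene, -1.18 to 0.082 for phenylpropanoids and -2.36 to 0.44 for heat shock. For list medians 503 values under alternatives kept sign and side of the threshold, 47 lost the call and 13 turned. For the 69 combinations of a named gene and a comparison, 852 values kept both, 119 passed only under the alternative, 71 lost the call and 0 turned. A single library that remains in a group is assumed to vary like the others. Apart from the smaller number of libraries in those fits, the cause of the differences was not tested. A pseudocount alternative was not run, since counts were tested. The AHL13 percentages stayed within the SD carried over from the same libraries, a limit that leaving out a library can hardly exceed. Leaving out a WT library gave 20.1% to 32.1% in flg22-treated seedlings. The slope ratios stayed within the SD of the reported ratios. Counts of genes at least 4-fold changed in ahl13 stayed within 1.5 times.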

Other observations

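The tests of the biological process terms, of the fit over 3 pairs, of the fits without a WT pair and of the patterns below were chosen only after the result was seen, except for those of the share of 0s in the shallower library, of a deletion and of a second change in the line. When the flg22 response was fitted over 3 pairs, the ahl13 pair included, both rises and falls passed edgeR. In these 3 pairs 27 of 39 early PAMP-induced genes rose, as did 21 of 28 PAMP receptors and early signalling genes, 10 of 17 camalexin genes, 11 of 29 jasmonate signalling genes, 9 of 31 salicylic acid genes, 7 of 20 ethylene genes and 5 of 14 indole glucosinolate genes. Of the aliphatic glucosinolate genes 11 of 15 fell, led by their regulator MYB29 (log2 -3.33, edgeR adjusted p = 0.017), and FMOGSOX3 fell by 2.87. Auxin response genes fell in 8 of 20 cases and rose in 2, and SAUR21 fell by 2.86. Of the photosynthesis genes 17 of 37 fell. The kinase gene CIPK20 (log2 -3.31) and the carotenoid cleavage gene NCED4 (log2 -3.09) were also among the largest falls, while 0 of 11 heat shock genes passed edgeR there. By camera at the preset correlation 13 lists passed there, and 0 with the correlation estimated (lowest adjusted p = 0.248 with an estimated correlation).

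Biological process terms were tested too. In WT after flg22, 60 of 658 terms passed camera at the preset correlation, led by response to oomycetes (24 genes, median log2 2.34, adjusted p = 4.8e-14), and 0 with the correlation estimated (adjusted p = 0.887 with an estimated correlation). Over 3 pairs, response to wounding (63 genes, median 0.66) and cellular response to hypoxia (46 genes, 1.095) lay higher and light harvesting in photosynthesis (20 genes, -0.67) lower, among 63 terms past camera at the preset correlation and 0 with it estimated (adjusted p = 0.795 with an estimated correlation). In infected leaves 10 of 624 terms passed, with photosynthesis (72 genes, median -0.40), light harvesting (20 genes, -0.58) and chlorophyll biosynthesis (18 genes, -0.39) lower in ahl13, response to oomycetes (23 genes, 0.18) and cold acclimation (18 genes, 0.27) higher, and 0 terms past the threshold with the correlation estimated (adjusted p = 0.994 with an estimated correlation). With the WT replicate 1 seedling pair left out, a single library per genotype and treatment remained, so that fit has no replicate check. Genes lower in ahl13 seedlings there included the nitrate transporter NRT2.1 (log2 -4.92), the ferric reductase FRO5 (-4.14) and the aquaporin PIP1;5 (-1.67). The ethylene synthesis gene ACS8 was at -1.63. The size of the fall for NRT2.1 and FRO5 rests on WT replicate 2: NRT2.1 was at 11.2 and 9.15 CPM there, at 0.66 and 1.12 CPM in WT replicate 1 and at 0.30 and 0.36 CPM in ahl13, and FRO5 at 39.4 and 43.5, 4.83 and 5.28, and 1.67 and 3.13 CPM. Photosynthesis genes then had a median of -0.20 with 36 of 37 negative and 23 lower adjusted over the list alone (camera adjusted p = 4.2e-11, adjusted p = 0.744 with an estimated correlation). With the WT replicate 2 pair left out instead the median was 0.55 with 28 of 37 positive (camera adjusted p = 2.1e-06, adjusted p = 0.617 with an estimated correlation), so the direction depends on the WT pair.

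A first pattern was 47 genes at 0 counts in one library of a group and at 100 counts or more in the other, in 55 cases. Lower depth of the library with the 0 is argued against by the totals, which differed by at most 1.29-fold within a group, too little to turn 100 counts into 0. The share of cases with the 0 in the shallower library, a test set before, was 74.5% (95% interval 61.0% to 85.3%, exact binomial) and does not exclude depth by itself: the interval lies below the 90% set to count for depth but spans the 75% set to count against it. In leaves all 7 such genes (100%) have a near-identical copy or overlap another gene, against 8.69% of other genes (one-sided Fisher exact p = 3.8e-08). In 8 of 9 cases the sum with the partner differed by less than 2-fold, as for CYCP4;2 with 342 and 0 counts beside AT5G61660 with 0 and 364. That pair was counted from both sides and in both genotypes. Where the partner holds most counts, as for EXO70G1 (0 and 474 in sums of 3677 and 3608), the sum says little. Reads assigned to a single partner may therefore account for the leaf cases. In seedlings only 21.6% (8 of 37 annotated genes) have such a partner (one-sided Fisher exact p = 0.0128), and of the 46 zeros 24 lay in the untreated and 14 in the flg22-treated WT replicate 1 library, so the seedling cases stay open and no biological explanation was tested.

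A second pattern was that the WT replicate 1 seedling pair stood apart from the other 4 seedling libraries, which a mutant effect cannot explain since both are WT. A smaller share of roots in that pair would leave photosynthesis genes level or higher there, but they were lower than in replicate 2 by a median of at least 0.771 (quartiles 0.52 to 1.15 untreated and 0.044 to 1.26 after flg22, with 33 and 30 of 37 genes lower), beside root markers lower by 2.44. Another harvest time remains open: morning genes of the clock exceeded evening genes between the pairs by at least 1.14, but evening genes stayed near level (-0.15 and -0.076 over 8 genes). The differences between the replicates correlated at 0.493 across genes between untreated and flg22-treated seedlings, which is consistent with something shared by both libraries of the pair, such as a batch of plants or of library preparation. The labels name no batch, and a biological difference between the sets of plants was not tested.

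The last pattern was the set of 4 genes lower in every ahl13 library than in the WT libraries of the same condition. IAA16 and AT3G05220 lie on chromosome 3 with 72 loci between them. A deletion across that stretch is argued against by the 44 genes measured there in leaves. Their median log2 change was 0.028 (quartiles -0.16 and 0.11) with 0 lower by 2-fold. AT3G04930, numbered between them, was at 3.69 CPM in the flg22-treated ahl13 library, against 101 and 77.3 CPM in WT. In untreated ahl13 seedlings it was at 59.2 CPM, and in leaves at 61.9 and 64.6 CPM against 58.7 and 58.5 in WT. Shared reads are argued against too, since 0 of the 4 genes have a near-identical copy or overlap another gene. An effect of AHL13 on these genes and a second change carried by the line cannot be told apart here, because the samples hold 1 mutant allele of AHL13. The genes are thus a hypothesis for targets that might depend on AHL13, to be tested in another allele or a complemented line.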
